A study of Mus musculus with 10 samples.

How the data were processed

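Pancreatic islets of sedentary and treadmill-exercised mice were measured by RNA-seq in 10 libraries, 5 per group. Per the labels' protocols, total RNA was extracted with a column kit for small samples and stranded mRNA libraries were prepared. The deposited table held the authors' estimated counts per Ensembl gene for each library, made from reads before deposit. The tools fastp and kallisto are named in the submitters' processing notes, without versions. The genome build, the annotation release and the way transcripts were summed to genes are not given in the sources used here. Of all values, 12.6% were not whole (tolerance 1e-06), and the estimated counts were rounded to whole numbers before testing. The table held 52178 genes, of which 28459 had a count in at least 1 library and 97.8% of these had a symbol in the table of gene names used. Genes without a symbol took at most 0.499% of the counts of a library. For 14 genes with over 100 counts all values equalled those of another gene (tolerance 0.001), so that genes sharing reads with near-identical copies are uncertain. Groups were taken from the labels, and no column was left without a sample.

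Library totals lay between 15081922 and 23222704 counts. Intervals from counts cover counting error only, since reads without molecular identifiers are not independent molecules. Over the 45 pairs of libraries the smallest chi-square per degree of freedom was 8.95 and the highest Spearman correlation across genes was 0.935, so no pair agreed within sampling noise. On log2 CPM the first principal component took 66.6% and the second 13.1% of the variance. The labels give no batch, day or litter, and replicate numbers run from 1 to 10 without a number shared by the groups.

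Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after its default filter on low counts (minimum count 10, minimum total 15), which left 15298 genes. Library sizes were scaled by trimmed mean of M-values (TMM) factors, which lay between 0.669 and 1.20, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. The 8-library fit named in the text is that without sedentary 1 and 2. The 29 gene lists, the tests, the rule for named genes and most alternatives were set before the data were examined. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry in its directional and mixed forms. Shares of counts and the senescence and SASP scores were compared with exact two-sided permutation tests, adjusted over 5 shares and over both scores.

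Named genes were of 3 kinds. The first were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and a symbol that is not a predicted or clone-based name. The second were the 4 members of smallest p of each list that passed its test or held a member that passed, and for other cell types the most abundant members. The third was a set given whatever it showed (insulin, glucagon, somatostatin and pancreatic polypeptide genes, Mafa, Pdx1, Slc2a2, Glp1r, Cdkn1a, Cdkn2a, Cdkn2b, Glb1, Igf1r, Bambi, Prkaa1, Prkaa2, Ppargc1a and Cpt1a). Genes named outside this rule are said to be picked after their values were seen. The rule named 131 genes, of which 130 could be tested and 84 passed. The values of some genes, most of them named by the rule, are not reported here, and counts include these genes.

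Alternatives were other scalings (RLE size factors, library totals, upper quartile), other filters on low counts, the acinar list or 1 surrogate variable (sva 3.50.0) as a covariate, DESeq2 1.42.0, limma-voom with and without sample quality weights, robust edgeR, other list tests, other scales of shares and scores, and leaving out each library in turn. Chosen after seeing the data were the 8 libraries without sedentary 1 and 2, the intestinal and secretory granule lists as covariates, acinar genes taken out before scaling, libraries thinned to the smallest total, and 3 added gene lists (small intestinal epithelium, glucocorticoid-responsive genes, and targets of the transcription factor ATF4).

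The edgeR step was tested on simulated data for this comparison, with counts drawn for 15298 genes. At the spread fitted to the 10 libraries, 18 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered, and 10 unchanged genes were called. At the spread fitted without sedentary 1 and 2, 70 and 92 of 100 were recovered, and 9 unchanged genes were called.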

Results

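Gene expression was measured in pancreatic islets, the clusters of endocrine cells that secrete insulin and glucagon, isolated from male C57Bl/6 mice that were retired breeders. There were 10 RNA-seq libraries, 5 from the sedentary group (sedentary 1 to 5) and 5 from the exercise group (exercise 6 to 10). The exercise group had run on a treadmill for 1 h a day on 5 days of each week over 2 weeks, at 17 cm/s on a slope of 5 degrees, after 3 days of acclimatization. Islets were freed by collagenase, picked by hand and kept in medium with 11 mM glucose. The series title names AMPK, the kinase that responds to low cellular energy, and senescence, a lasting arrest of the cell cycle, as its subjects. The comparison of exercise with sedentary islets asked which genes differed, with these 2 subjects among the fixed gene lists. The sedentary libraries held 15795871, 16855845, 15081922, 20670174 and 17226558 counts. The exercise libraries held 21207404, 16461369, 17998054, 23222704 and 19352104 counts. Values in counts scaled to library size (CPM) are group means ± SD with n = 5 libraries per group. The labels do not tie each library to its own animal, so p-values measure the spread between libraries, which may be partly technical. Genomic positions are not printed because the genome build behind the counts is not given in the sources used here.

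The groups differed in how their counts were divided among cell types. The acinar list, 34 genes of the enzyme-secreting exocrine pancreas, took 16.3 ± 4.52% of counts in sedentary and 30.1 ± 7.28% in exercise libraries (mean ± SD, n = 5 each, exact two-sided permutation test, p = 0.00794, the smallest it can give, adjusted p = 0.0198 over 5 shares). The 10 most abundant genes of each library took 26.3 ± 7.93% in sedentary and 38.4 ± 3.40% in exercise libraries (adjusted p = 0.0198, exact permutation test). Mitochondrially encoded genes took 4.84 ± 2.41% in sedentary and 2.45 ± 0.486% in exercise libraries (adjusted p = 0.0265, exact permutation test). Insulin, from Ins1 and Ins2, took 11.7 ± 9.02% and 13.7 ± 3.29% (adjusted p = 0.667, exact permutation test), and glucagon 0.662 ± 0.675% and 0.398 ± 0.0925% (adjusted p = 0.667, exact permutation test). Within the sedentary group the insulin share was 0.757% in sedentary 1 and 3.67% in sedentary 2, against 14.8, 18.3 and 21.1% in sedentary 3, 4 and 5, while the exercise libraries lay between 8.03 and 16.1%. Without sedentary 1 and 2, a set of 8 libraries chosen after seeing the data, the acinar share still differed (adjusted p = 0.0446, exact permutation test). The glucagon share then differed by -0.627 percentage points (adjusted p = 0.0446, exact permutation test). It was 0.632, 0.680 and 1.76% in sedentary 3, 4 and 5 and 0.272 to 0.479% in exercise. The glucagon gene Gcg did not pass the gene test in these 8 libraries (edgeR adjusted p = 0.0964). The insulin share, 18.1% on average in sedentary 3 to 5, differed by -4.34 points and did not pass (adjusted p = 0.107, exact permutation test). The mitochondrial share (adjusted p = 0.107) and the share of the 10 most abundant genes (adjusted p = 0.0893) no longer passed, all by exact permutation. With 1 library left out, the acinar call was lost without exercise 6 or 9 and that of the 10 most abundant genes without any 1 exercise library (exact permutation adjusted p = 0.0595 each). The mitochondrial call was lost without any 1 exercise library (exact permutation adjusted p = 0.146 to 0.225).

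Transcripts of the small intestinal epithelium were abundant in the sedentary libraries and scarce in the exercise libraries. A list of 40 such genes, written after the data were seen, had 39 tested members, of which 35 fell and 0 rose in exercise. Their median log2 fold change was -4.47 (limma camera adjusted p = 9.4e-22 over 3 added lists; adjusted p = 0.0884 with an estimated correlation). Adjusted over the list alone, 37 fell and 1 rose. These members were picked after their values were seen. Apoa4, an apolipoprotein of chylomicrons, had 2076 ± 1500 CPM in sedentary and 119 ± 98.3 in exercise libraries, and Fabp2, the intestinal fatty acid binding protein, 855 ± 768 and 25.7 ± 18.9 CPM. Sis, encoding the brush border enzyme sucrase-isomaltase, had 424 ± 395 and 15.5 ± 9.55 CPM. The list's mean log2 CPM was 7.86 in sedentary 1, 8.59 in sedentary 2, 6.33 in sedentary 3, 5.70 in sedentary 4 and 6.32 in sedentary 5, and lay between 2.06 and 3.95 in the exercise libraries. In the 8 libraries without sedentary 1 and 2, 35 of 40 tested members fell and the median was -3.06.

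**Figure D1:**
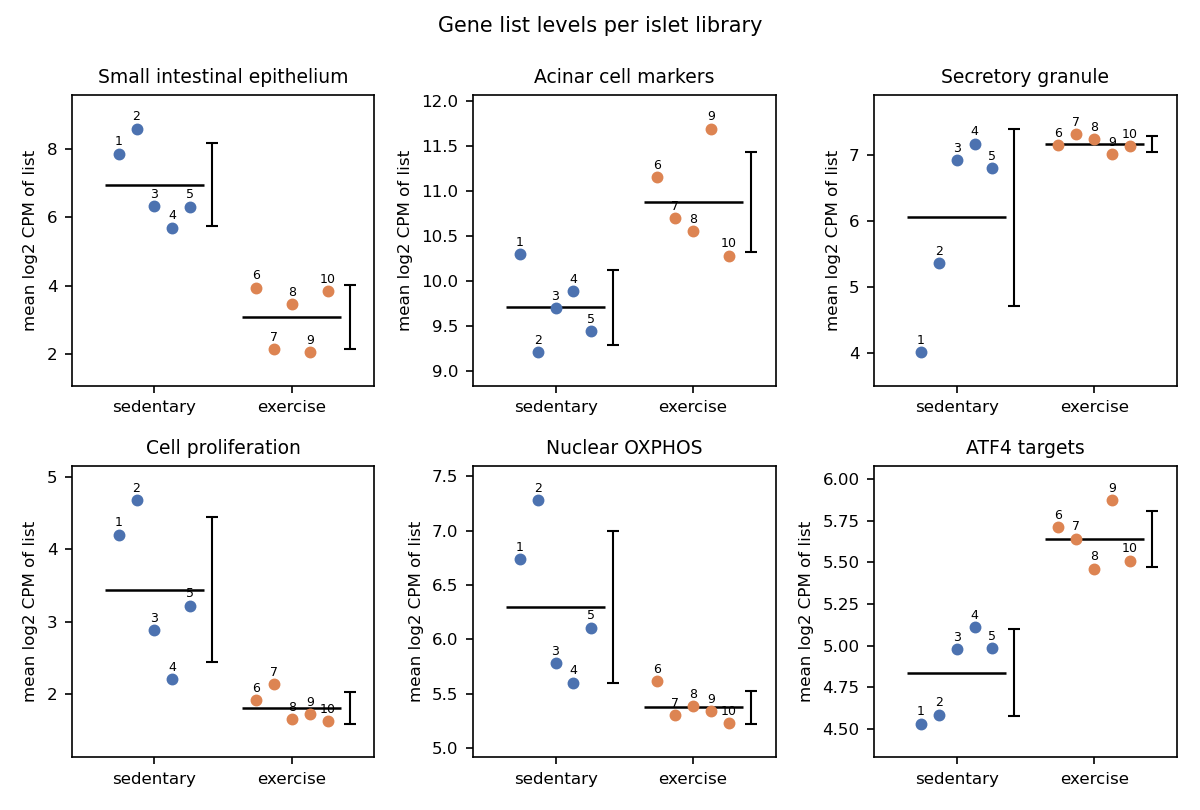
Mean log2 CPM over the members of 6 gene lists (vertical axes) in the sedentary (blue) and exercise (orange) islet libraries. Each numbered point is 1 library, horizontal bars are group means and error bars are SD (n = 5). The intestinal list lies between 5.70 and 8.59 in sedentary and between 2.06 and 3.95 in exercise libraries.

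Of 15298 genes tested, 374 were higher and 1745 lower in exercise than in sedentary islets (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), so that 82.4% of the changed genes were lower. The largest rise was that of Zbtb16 (ENSMUSG00000066687), a zinc finger transcription factor, from 0.661 ± 0.408 to 16.7 ± 7.90 CPM, a log2 fold change of 4.63 ± 0.51 (SE, edgeR adjusted p = 0.00900). The chemokine genes Ccl7 and Ccl2, which attract monocytes, followed at 4.06 and 3.59, and exercise 6 held the highest Ccl2 level, 23.5 CPM. Fam107a, an actin-associated stress-induced gene, rose from 3.29 ± 1.78 to 34.1 ± 16.9 CPM. The lipid droplet gene Plin4 (log2 fold change 3.01), Hif3a of the hypoxia-inducible factor family (2.93), the acid-sensing channel gene Asic2 (2.90), Asb9 (2.79), the pentraxin gene Nptx2 (2.79) and Klhdc8a (2.78) completed the 10 largest rises.

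The 10 largest falls included genes of the stomach and of intestinal Paneth cells. Pgc, encoding the stomach proenzyme progastricsin, had a log2 fold change of -10.10. It rested on sedentary 1 at 2842 CPM, where the other sedentary libraries lay between 6.46 and 43.4 CPM, and was -4.98 without it. Its call was lost without exercise 7, 8, 9 or 10 (highest edgeR adjusted p = 0.0664). The alpha-defensin genes of intestinal Paneth cells Defa36 (-7.80), Defa23 (-6.81), Defa30 (-6.63) and Defa24 (-6.57) and the defensin-related AY761184 (-6.53) are near copies of each other, so the division of reads among them is uncertain. Slc5a12 (-6.51), a monocarboxylate transporter, Clca3b (-6.47), the antimicrobial gene Ang4 (-6.43) and the lectin gene Itln1 (-6.39) followed. The calls of Defa23, Defa24 and Itln1 were lost without exercise 7, 8, 9 or 10, that of AY761184 without exercise 7, 8 or 9 and that of Defa30 without exercise 8 (highest edgeR adjusted p = 0.0590, 0.0617, 0.0640, 0.0562 and 0.0530). Without sedentary 2 their log2 fold changes were -4.97, -4.87, -4.68, -4.77 and -4.82, in the same order of genes, and without exercise 6 they were -10.09, -10.19, -12.55, -9.68 and -9.10. Defa36 had 623 counts over the sedentary and 2 over the exercise libraries. Per count of TMM-scaled library size this was a ratio of 279 (95% counting interval 77.0 to 2311). Slc5a12 had 362 and 3, a ratio of 108 (36.7 to 527) on the same scale.

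Without sedentary 1 and 2, 644 genes were higher and 1362 lower of 15692 tested, and 312 higher and 1288 lower genes were shared with the fit of all 10 libraries, none in opposite directions. With scaling to library totals alone, in place of trimmed-mean (TMM) factors, 159 genes were higher and 4408 lower, or 96.5% lower. With the mean level of the acinar list as a covariate, 0 genes passed in either direction (edgeR, 1867 at an unadjusted p under 0.05); DESeq2 and limma-voom without this covariate called 3739 and 516 genes. Of 52 named genes that fell, 40 had a log2 fold change over 1.5 times larger with all libraries than without sedentary 1 and 2, as had 0 of the named genes that rose. The acinar covariate shared much of its variance with the group (r squared 0.638). With the level of the intestinal list as a covariate, chosen after seeing the data, edgeR called 0 genes too (279 at an unadjusted p under 0.05). Of the 84 named genes that had passed without it, 37 changed sign. The intestinal level shared even more of its variance with the group (r squared 0.801).

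**Figure D2:**
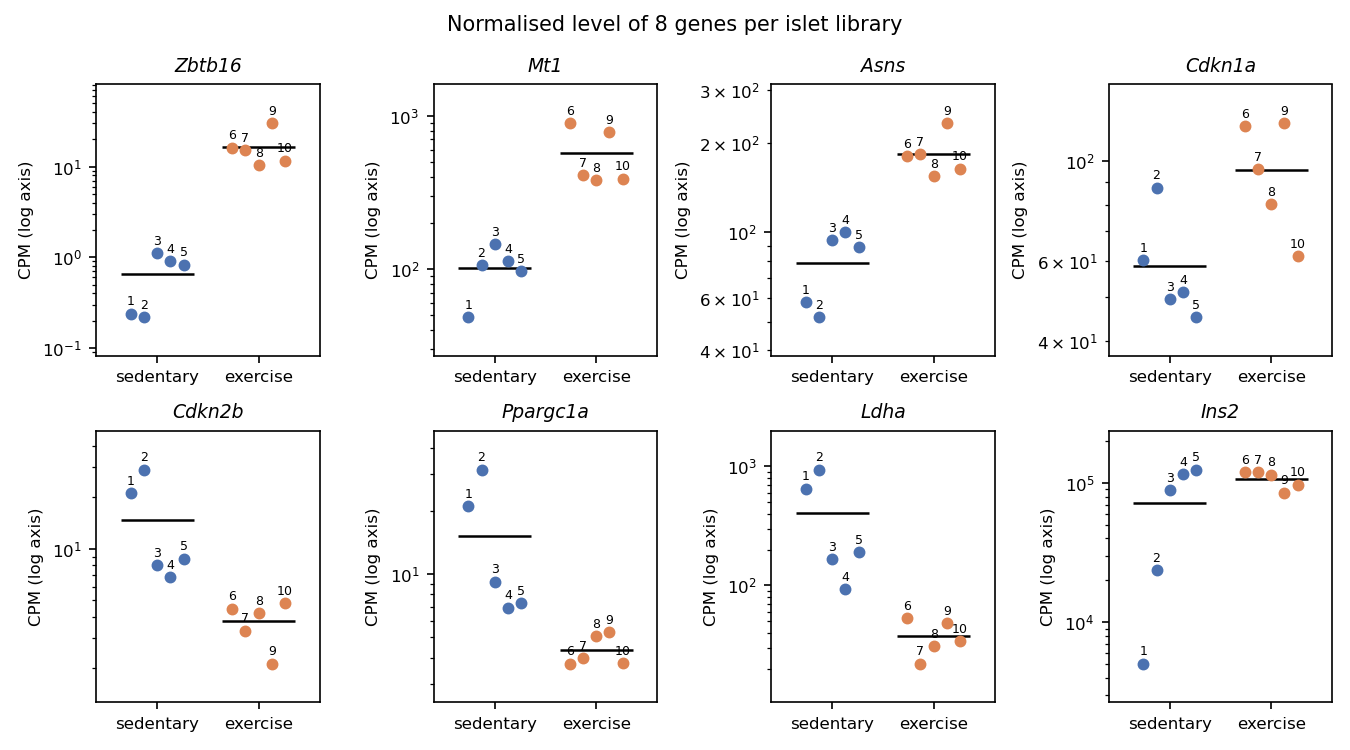
CPM of 8 genes (vertical log axes) in the sedentary (blue) and exercise (orange) islet libraries. Each numbered point is 1 library and horizontal bars are group means (n = 5). Zbtb16 lies between 0.218 and 1.11 CPM in sedentary and between 10.4 and 30.1 CPM in exercise libraries.

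Of the 29 gene lists fixed before the data were examined, 28 had at least 3 tested members, and 14 of these passed limma's camera test with its preset correlation of 0.01, 5 toward exercise and 9 toward sedentary. None of the 14 passed with an estimated correlation between members (adjusted p = 0.679 for each), and 6 lists passed fry's directional test. Fry's mixed test, which asks for changes in either direction and so gives no direction, was passed by 16 lists. Other divisions of the same 10 libraries into 5 and 5 passed between 5 and 19 lists, and 39 of 100 divisions passed at least 14, the real one included. The same 100 divisions gave at most 1 changed gene apart from the real one with 2119. With 1 surrogate variable as a covariate the calls of the beta cell identity (camera adjusted p = 0.909), secretory granule (0.488), endothelial (0.141), lymphocyte (0.0805), glycolysis (0.124) and ribosomal (0.708) lists were lost. The same 6 calls were lost with the granule list as a covariate (camera adjusted p = 0.994, 0.692, 0.0768, 0.128, 0.180 and 0.606). The loss of the granule list itself was fixed in advance, since the covariate is that list's mean level. With the acinar covariate 15 lists passed, 10 of them lists that passed without it in the same direction, and with the intestinal covariate 15 passed, of which 2 did so. Both covariates follow the group, and these passes were tested at the preset correlation alone. They therefore establish no direction for any list, here or where they are given below. The counts of single members that passed edgeR's test are therefore given first for each list.

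Genes of the senescence program went in both directions. Of 25 tested members of the senescence and cell cycle arrest list, 3 rose, 2 fell and 20 did not pass (adjusted over the list alone, 4 rose and 3 fell). Its median log2 fold change was 0.09 and its mean -0.04, and the list test did not pass (camera adjusted p = 0.549, toward exercise). It passed fry's mixed test, which gives no direction (fry mixed adjusted p = 0.0114). Cdkn2b (ENSMUSG00000073802), encoding the cyclin-dependent kinase inhibitor p15, fell from 14.8 ± 9.86 to 3.78 ± 1.07 CPM (log2 fold change -1.96 ± 0.44 SE, edgeR adjusted p = 0.0186) and was lower in each exercise library than in any sedentary library. It was at 21.2 and 29.0 CPM in sedentary 1 and 2, the libraries with the highest intestinal levels, and between 6.82 and 8.76 CPM in sedentary 3 to 5. Its log2 fold change was -1.03 without sedentary 1 and 2 and 0.76 with the intestinal level as a covariate, and its call was lost without exercise 7 or 9 (highest edgeR adjusted p = 0.0544). The survival gene Bcl2l1 rose from 33.2 ± 5.72 to 53.0 ± 7.35 CPM, and the growth arrest genes Btg2 (log2 fold change 0.83) and Gadd45b (1.15) also rose. The call of Bcl2l1 was lost without exercise 6, 8 or 9 (highest edgeR adjusted p = 0.0551), that of Btg2 without sedentary 1, 2, 3 or 5 or exercise 6 or 7 (0.0685) and that of Gadd45b without sedentary 1, 2 or 5 or exercise 6, 7, 8 or 9 (0.0869). Neither Btg2 nor Gadd45b passed without sedentary 1 and 2 (edgeR adjusted p = 0.0585 and 0.0785). Lmnb1, encoding the nuclear lamina protein lamin B1, was the other member that fell, by 1.38 on the log2 scale (edgeR adjusted p = 0.0452), and was picked after its value was seen. Cdkn1a (ENSMUSG00000023067), encoding the kinase inhibitor p21, had 58.6 ± 16.9 and 95.6 ± 25.6 CPM (log2 fold change 0.71 ± 0.24 SE, edgeR adjusted p = 0.0712), and rose by 1.00 without sedentary 1 and 2 (edgeR adjusted p = 0.0124). Cdkn2a, the locus of p16 and the most used marker of senescence, was too low to be tested, at 0.570 ± 0.209 and 0.353 ± 0.185 CPM. Glb1, which encodes lysosomal beta-galactosidase, had 33.7 ± 6.32 and 29.7 ± 3.64 CPM and Igf1r 23.2 ± 10.0 and 34.8 ± 3.69 CPM. Bambi, a decoy receptor of the TGF-beta pathway, had 21.4 ± 15.2 and 36.2 ± 7.49 CPM. None of these passed (edgeR adjusted p = 0.383, 0.171 and 0.336).

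The senescence-associated secretory phenotype (SASP) list, of cytokines, proteases and growth factors released by senescent cells, had 86 tested members, of which 5 rose and 12 fell (adjusted over the list alone, 6 rose and 13 fell). Its median log2 fold change was -0.09 and its list test did not pass (camera adjusted p = 0.898), while fry's mixed test did (fry mixed adjusted p = 0.0114). Without sedentary 1 and 2, 7 of 91 tested members rose and 7 fell, with a median of -0.07. Il18 fell from 21.5 ± 19.1 to 1.97 ± 0.652 CPM and Il15 from 4.73 ± 4.05 to 0.466 ± 0.262 CPM. Il18 was at 34.9 and 48.4 CPM and Il15 at 6.27 and 11.1 CPM in sedentary 1 and 2, where the intestinal list was highest, against 4.88 to 9.94 and 1.30 to 2.55 CPM in sedentary 3 to 5. Their log2 fold changes of -3.44 and -3.31 were -2.01 and -2.08 without sedentary 1 and 2, and 0.39 and 0.16 with the intestinal level as a covariate. The peptidase gene Dpp4 fell from 101 ± 43.5 to 39.8 ± 6.27 CPM (log2 fold change -1.34, and -0.79 without sedentary 1 and 2), while Gem, a small GTP-binding protein gene, rose from 3.53 ± 1.19 to 11.1 ± 3.65 CPM. The other rises were those of Ccl2 and Ccl7, named above, and of Cxcl2 (log2 fold change 2.77) and the growth factor gene Csf1 (0.99), the latter pair picked after their values were seen. The score of the senescence list per library, its mean centred log2 CPM, was -0.0185 ± 0.0541 in sedentary and 0.0185 ± 0.0643 in exercise libraries (n = 5 each, exact two-sided permutation test, p = 0.365, adjusted p = 0.730). The SASP score was 0.0113 ± 0.283 and -0.0113 ± 0.235 (p = 0.881, adjusted p = 0.881, exact permutation test). The senescence score changed direction with scaling to library totals alone, to a difference of -0.31 (exact permutation adjusted p = 0.0159). With each gene scaled to unit variance it passed toward exercise, with a difference of 0.15 (exact permutation adjusted p = 0.0317). The SASP median changed sign with upper-quartile scaling, to 0.02, and the SASP list passed toward sedentary with the acinar covariate (median -0.35, camera adjusted p = 0.0273).

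Of the AMPK list, the kinase's subunits, upstream kinases and targets, 3 of 34 tested members rose and 1 fell, over all genes as well as adjusted over the list alone. Foxo3, a transcription factor that AMPK phosphorylates, rose from 47.3 ± 5.14 to 83.3 ± 25.1 CPM (log2 fold change 0.81). The autophagy kinase gene Ulk1 rose from 37.5 ± 8.51 to 58.9 ± 5.75 CPM (0.65) and the upstream kinase gene Camkk2 from 12.8 ± 3.95 to 22.4 ± 2.52 CPM (0.81). Ppargc1a (ENSMUSG00000029167), encoding the mitochondrial coactivator PGC-1alpha, fell from 15.2 ± 10.8 to 4.36 ± 0.747 CPM (log2 fold change -1.79 ± 0.43 SE, edgeR adjusted p = 0.0237). It was at 21.04 and 31.4 CPM in sedentary 1 and 2, the libraries with the highest intestinal levels, and between 6.91 and 9.21 CPM in sedentary 3 to 5. Its log2 fold change was -0.81 without sedentary 1 and 2 and 0.38 with the intestinal level as a covariate. The catalytic subunit genes Prkaa1, at 44.5 ± 14.9 and 57.1 ± 5.92 CPM, and Prkaa2, at 17.4 ± 7.60 and 15.1 ± 2.59 CPM, did not pass (edgeR adjusted p = 0.272 and 0.628). Nor did the fatty acid oxidation gene Cpt1a, at 124 ± 91.6 and 69.0 ± 9.95 CPM (edgeR adjusted p = 0.185). The list test did not pass (median 0.15, camera adjusted p = 0.0756; adjusted p = 0.679 with an estimated correlation). At the preset correlation it passed without sedentary 1 and 2 (camera adjusted p = 0.0157), without sedentary 2 alone (0.0366), with upper-quartile scaling (0.0488) and with no filter on low counts (0.0285). It also passed with a surrogate variable (0.0137) or the granule list (0.0157) as a covariate. With an estimated correlation the list did not pass without sedentary 1 and 2 either (adjusted p = 0.687). With all 10 libraries it passed fry's mixed test (fry mixed adjusted p = 0.0260). The AMPK list's mean log2 CPM lay between 4.48 and 4.69 in sedentary and between 4.71 and 4.84 in exercise libraries. An exact permutation test of these levels, not set beforehand for this list, gave an unadjusted p = 0.00794. The medians of the senescence and AMPK lists changed sign with scaling to library totals alone, to -0.24 and -0.20. The call of Camkk2 was lost without sedentary 2 or 5 or any 1 exercise library (highest edgeR adjusted p = 0.0819) and that of Ppargc1a without sedentary 1 or any 1 exercise library (0.0643). That of Ulk1 was lost without sedentary 5 or exercise 6, 7, 8 or 9 (0.0695) and that of Foxo3 without exercise 6 or 7 (0.0576).

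None of 28 tested beta cell identity genes passed over all genes or adjusted over the list alone, although the list stood higher in exercise (median log2 fold change 0.70, camera adjusted p = 4.2e-05; adjusted p = 0.679 with an estimated correlation). Ins2 had 71445 ± 54130 and 107499 ± 15668 CPM and Ins1 29733 ± 22800 and 44687 ± 7057 CPM, both with log2 fold changes of 0.59, and of 0.00 without sedentary 1 and 2. Neurod1, a transcription factor of endocrine cells, had 40.1 ± 26.2 and 123 ± 17.6 CPM. Pdx1 had 53.9 ± 16.9 and 81.5 ± 12.9 CPM and the granule gene Sytl4 98.0 ± 66.4 and 245 ± 23.3 CPM. None of these passed, with edgeR adjusted p between 0.0651 and 0.111. Mafa (89.1 ± 62.0 and 97.5 ± 41.4 CPM), the glucose transporter gene Slc2a2 (347 ± 128 and 332 ± 60.1 CPM) and the incretin receptor gene Glp1r (247 ± 149 and 239 ± 45.7 CPM) lay within their spread. All 3 were lower in sedentary 1 and 2 than in the other sedentary libraries. Mafa was at 11.2 and 34.3 CPM in sedentary 1 and 2, 121 to 149 in sedentary 3 to 5 and 52.5 to 162 in exercise. In the same order Slc2a2 was at 195 and 250, 344 to 497 and 256 to 398 CPM. Glp1r was at 33.5 and 167, 271 to 394 and 166 to 287 CPM. The beta cell median was 0.42 without sedentary 1, and -1.08 with the intestinal covariate, where the list passed toward sedentary at the preset correlation (camera adjusted p = 1.7e-05). The sign of the log2 fold changes of Mafa, Slc2a2 and Glp1r turned under library totals (Mafa) or upper-quartile scaling (Slc2a2 and Glp1r). Without sedentary 1 and 2 the beta cell median was 0.18 and 5 members rose, among them Neurod1 and Sytl4 by 1.11 and 0.78 and, picked after their values were seen, Rfx6 (0.71) and G6pc2 (0.85).

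The secretory granule and exocytosis list had 0 of 30 members past the edgeR test over all genes or adjusted over the list alone. Its median was 0.74 (camera adjusted p = 8.2e-06; adjusted p = 0.679 with an estimated correlation), 0.44 without sedentary 1, -1.16 with the intestinal covariate (camera adjusted p = 5.2e-06, toward sedentary) and 0.21 without sedentary 1 and 2, where Rab27a rose and, picked after their values were seen, Unc13a and Rph3al. Its members of smallest p were the syntaxin gene Stx1a (log2 fold change 0.82), Unc13b (0.43), the granule transport gene Rab27a (0.96) and the calcium channel gene Cacna1d (1.14). In the alpha cell list 1 of 9 members rose, Slc38a5, a glutamine transporter gene, from 14.2 ± 3.47 to 26.1 ± 6.93 CPM, also when adjusted over the list alone, and the list did not pass (median 0.09, camera adjusted p = 0.0937). The call of Slc38a5 was lost without sedentary 2, 3 or 5 or exercise 6, 7 or 9 (highest edgeR adjusted p = 0.0730). Gcg, the glucagon gene, had 5684 ± 5659 and 4460 ± 802 CPM and Ttr 535 ± 461 and 781 ± 111 CPM. Slc7a2 and Gc, the next members by p, had log2 fold changes of 1.09 and 0.97 and did not pass. None of 7 delta and PP cell markers passed over all genes or adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.171). Leaving out 1 library moved that median between -0.01 and 0.76. The somatostatin gene Sst was at 1152 ± 935 and 1373 ± 352 CPM and the pancreatic polypeptide gene Ppy at 876 ± 660 and 1333 ± 534 CPM. With library totals alone the medians of the alpha and the delta and PP lists became -0.26 and -0.09, although both lists then passed toward exercise relative to the other genes (camera adjusted p = 0.0142 and 0.0327), and Sst changed sign to -0.13. The alpha list also passed with no filter on low counts (0.0322), with the acinar covariate (0.0363) and without sedentary 5 (0.0293). The alpha and the delta and PP medians were -0.04 and -0.28 without sedentary 1 and 2 (camera adjusted p = 0.970 and 0.628). With the intestinal covariate the delta and PP median was -1.38 (camera adjusted p = 0.00719).

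Beta cell disallowed genes, which mature beta cells keep at low levels, were lower in exercise. Of 17 tested members 8 fell, 0 rose and 9 did not pass (adjusted over the list alone, 9 fell), with a median log2 fold change of -1.34 (camera adjusted p = 7.1e-05; adjusted p = 0.679 with an estimated correlation). Ldha, the lactate dehydrogenase subunit gene, fell from 407 ± 368 to 37.6 ± 12.8 CPM and the monocarboxylate transporter gene Slc16a1 from 30.2 ± 28.6 to 2.28 ± 0.555 CPM. The catalase gene Cat fell from 166 ± 132 to 20.1 ± 3.01 CPM. Of the members 7 fell without sedentary 1 and 2, where the median was -0.66, and with the intestinal covariate the median was 0.28 and the list did not pass (camera adjusted p = 0.581). Ldha was at 648 and 935 CPM in sedentary 1 and 2, the libraries with the highest levels of the intestinal list.

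Acinar genes were higher in exercise. Of 34 acinar markers 18 rose and 0 fell (adjusted over the list alone, 30 rose), with a median log2 fold change of 1.25 (camera adjusted p = 3.4e-13; adjusted p = 0.679 with an estimated correlation). The kallikrein gene Klk1 rose from 831 ± 213 to 2680 ± 1143 CPM and Ptf1a, a transcription factor of acinar cells, from 5.63 ± 2.66 to 23.7 ± 12.5 CPM. The chymotrypsin-like gene Ctrl rose from 4034 ± 1167 to 10735 ± 4358 CPM and Sycn, encoding a zymogen granule protein, from 1280 ± 283 to 3542 ± 1858 CPM. Amy2a5, the most abundant marker, rose from 20699 ± 6734 to 61915 ± 32905 CPM, and shares reads with near-identical amylase copies. In the 8-library fit 21 rose and the median was 1.37. The call of Ctrl was lost without sedentary 2 or 5 or exercise 6, 7 or 9 (highest edgeR adjusted p = 0.0627) and that of Sycn without sedentary 2 or 5 or exercise 6 or 9 (0.0632).

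Markers of other cell types moved less evenly. Of 14 ductal markers 3 fell, also when adjusted over the list alone. These were Cftr (39.9 ± 46.9 to 2.01 ± 1.76 CPM), the bicarbonate transporter gene Slc4a4 (47.6 ± 39.8 to 8.14 ± 0.874 CPM) and Krt19 (319 ± 340 to 18.7 ± 15.4 CPM), all of which the intestinal epithelium also expresses. The list's median was 0.02 (-0.35 with library totals alone), its mean -0.76 and its camera adjusted p = 0.700, toward sedentary. Sox9, at 8.51 ± 8.29 and 2.51 ± 1.603 CPM, did not pass. None of 18 endothelial markers passed over all genes or adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.00224; adjusted p = 0.679 with an estimated correlation) that was 0.15 without sedentary 1 and 2 (camera adjusted p = 0.0975) and 0.27 without sedentary 2. That call was also lost with the acinar covariate (camera adjusted p = 0.140), and with the intestinal covariate the median was -0.69 (camera adjusted p = 0.000524, toward sedentary). Its members of smallest p were Ptprb (log2 fold change 0.95), Erg (0.70), Flt1 (0.99) and Sox17 (1.09). Of 17 lymphocyte markers 1 fell, also when adjusted over the list alone: Cd8a, a marker of cytotoxic T cells, from 14.8 ± 18.6 to 0.970 ± 0.791 CPM. That list's median was -2.34 (camera adjusted p = 0.00767; adjusted p = 0.679 with an estimated correlation), and it no longer passed with library totals alone (camera adjusted p = 0.139). The median was -1.02 without sedentary 1, where the list's mean log2 CPM was 6.54 against 1.88 to 4.72 in the other sedentary libraries, and -1.05 without sedentary 1 and 2. Cd8a had a log2 fold change of -3.91, and of -2.30 without sedentary 1 and 2, and its call was lost without exercise 7 or 8 (highest edgeR adjusted p = 0.0515). Cd3g, Nkg7 and Cd5 had log2 fold changes of -2.60, -2.39 and -2.77 (-1.50, -1.42 and -1.33 without sedentary 1) and did not pass. Of 22 macrophage and antigen presentation markers 1 rose, Cd14, the lipopolysaccharide co-receptor gene, from 3.12 ± 0.9004 to 13.4 ± 10.2 CPM, also when adjusted over the list alone (edgeR adjusted p = 0.0516 without sedentary 1 and 2). Mrc1 (log2 fold change 1.75), Itgax (-1.11) and H2-Ab1 (-1.18, and -1.40 to -0.71 with 1 library left out) did not pass. The list's median of -0.14 (-0.38 to 0.32 with 1 library left out) and its camera direction, toward exercise, differed in sign (adjusted p = 0.865). It passed toward sedentary with the acinar (median -0.47, camera adjusted p = 0.0467) and the intestinal covariate (-0.63, 0.00370).

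None of 21 mesenchymal markers passed over all genes or adjusted over the list alone. Rgs5 was at 44.6 ± 25.7 and 61.9 ± 11.3 CPM and Sparc at 41.1 ± 19.2 and 44.5 ± 4.89 CPM. The median was -0.38, against a camera direction toward exercise (adjusted p = 0.700), and -1.16 with the intestinal covariate (camera adjusted p = 8.7e-07, toward sedentary). With 1 library left out it lay between -0.60 and 0.10. Of 4 Schwann cell markers Cdh19 rose from 0.431 ± 0.174 to 1.79 ± 0.626 CPM, also when adjusted over the list alone (list median 0.59, camera adjusted p = 0.0880; 0.0297, 0.0490 and 0.0260 without sedentary 1, 3 and 5, 0.0244 with library totals and 0.00977 with no filter on low counts), and no other member passed (Ngfr had a log2 fold change of -0.46). None of 5 red blood cell genes passed over all genes or adjusted over the list alone (median -1.18, camera adjusted p = 0.700). That median was -2.29 to -0.36 with 1 library left out and -3.09 with the intestinal covariate (camera adjusted p = 0.0134). Hbb-bs was at 141 ± 157 and 65.0 ± 82.3 CPM and Hba-a2 at 94.6 ± 105 and 41.6 ± 44.7 CPM. Only 2 adipocyte markers could be tested, of which the lipid droplet gene Cidec fell from 15.4 ± 12.2 to 1.48 ± 1.15 CPM, also when adjusted over the list alone, and Fabp4, at 9.23 ± 4.58 and 15.2 ± 5.52 CPM, did not pass. The call of Cidec was lost without exercise 8 (edgeR adjusted p = 0.0505).

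Many nuclear genes of mitochondrial energy metabolism were lower in exercise. Of 62 tested nuclear genes of oxidative phosphorylation 37 fell and 0 rose (adjusted over the list alone, 61 fell), with a median log2 fold change of -1.05 (camera adjusted p = 5.5e-14; adjusted p = 0.679 with an estimated correlation). The cytochrome c gene Cycs fell from 77.5 ± 52.6 to 22.7 ± 1.83 CPM, Cox5a from 84.9 ± 64.8 to 20.3 ± 5.38 CPM, Uqcrc1 from 232 ± 173 to 66.1 ± 6.94 CPM and Cyc1 from 153 ± 120 to 42.2 ± 5.15 CPM. Of 25 fatty acid oxidation genes 13 fell and 0 rose; adjusted over the list alone, 18 fell. The median was -1.31 (camera adjusted p = 3.8e-05; adjusted p = 0.679 with an estimated correlation). Examples were Acaa2 (136 ± 114 to 22.6 ± 4.04 CPM), Decr1 (log2 fold change -1.98) and the medium-chain dehydrogenase gene Acadm (-1.79). None of the 13 mitochondrially encoded genes passed over all genes or adjusted over the list alone (median -0.61, camera adjusted p = 0.165), and their median was 0.10 without sedentary 1 and 2. That list passed without sedentary 5 (camera adjusted p = 0.0269) and with the acinar covariate (median -0.84, camera adjusted p = 0.0155). With the intestinal covariate the medians of the oxidative phosphorylation, fatty acid oxidation and mitochondrially encoded lists turned to 0.62, 0.73 and 0.85, toward exercise (camera adjusted p = 1.3e-10, 8.6e-07 and 1.9e-05), and Cycs and Cyc1 had log2 fold changes of 0.69 and 0.85, not past the threshold. In the fit of 8 libraries the falls in oxidative phosphorylation numbered 27 (median -0.44), and 11 fatty acid oxidation genes fell and 2 rose, among them Eci2, picked after its value was seen (median -0.48). The mean log2 CPM over the oxidative phosphorylation list was 6.74 in sedentary 1 and 7.28 in sedentary 2, the libraries with the highest intestinal levels, against 5.60 to 6.11 in sedentary 3 to 5 and 5.22 to 5.62 in exercise. The calls of Cycs, Uqcrc1 and Cyc1 were lost without any 1 exercise library, that of Cyc1 also without sedentary 1, and those of Cox5a, Decr1 and Acadm without exercise 7, 8, 9 or 10 (edgeR adjusted p up to 0.0695).

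Of 31 glycolysis and hypoxia genes 11 fell and 1 rose; adjusted over the list alone, 15 fell and 4 rose. The median was -0.51 (camera adjusted p = 0.0292; adjusted p = 0.679 with an estimated correlation). Car9, a carbonic anhydrase induced by hypoxia, fell from 43.0 ± 42.9 to 1.65 ± 0.766 CPM and Pfkfb4, a regulator of glycolytic flux, from 35.9 ± 27.1 to 6.18 ± 1.01 CPM. The hypoxia-inducible prolyl hydroxylase gene Egln3 fell from 8.83 ± 6.998 to 1.30 ± 0.463 CPM, and Ldha is a member here too. The single rise was that of the mitophagy gene Bnip3 (28.9 ± 14.1 to 76.2 ± 16.4 CPM), picked after its value was seen. The list no longer passed without sedentary 1 (camera adjusted p = 0.0532, median -0.32), without sedentary 1 and 2 (0.0546, median -0.21) or with library totals alone (0.0719). With the intestinal covariate its median was 0.28 (camera adjusted p = 0.0776). Of 28 genes of lipid and cholesterol synthesis 9 fell and 0 rose; adjusted over the list alone, 10 fell. The median was -0.24 (camera adjusted p = 0.0272; adjusted p = 0.679 with an estimated correlation). The sterol enzyme gene Idi1 (29.6 ± 13.8 to 12.02 ± 1.24 CPM) fell. So did Cyp51 (32.7 ± 4.02 to 22.1 ± 2.19 CPM) and the cholesterol transfer gene Stard4 (47.7 ± 31.0 to 15.1 ± 1.77 CPM). That list no longer passed without sedentary 4 (camera adjusted p = 0.119), exercise 9 (0.0613) or exercise 10 (0.0683), nor with the acinar (0.0560) or intestinal covariate (0.134). The call of Idi1 was lost without exercise 9, that of Cyp51 without exercise 9 or 10 and that of Stard4 without any 1 exercise library (highest edgeR adjusted p = 0.0503, 0.0629 and 0.0581).

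**Figure D3:**
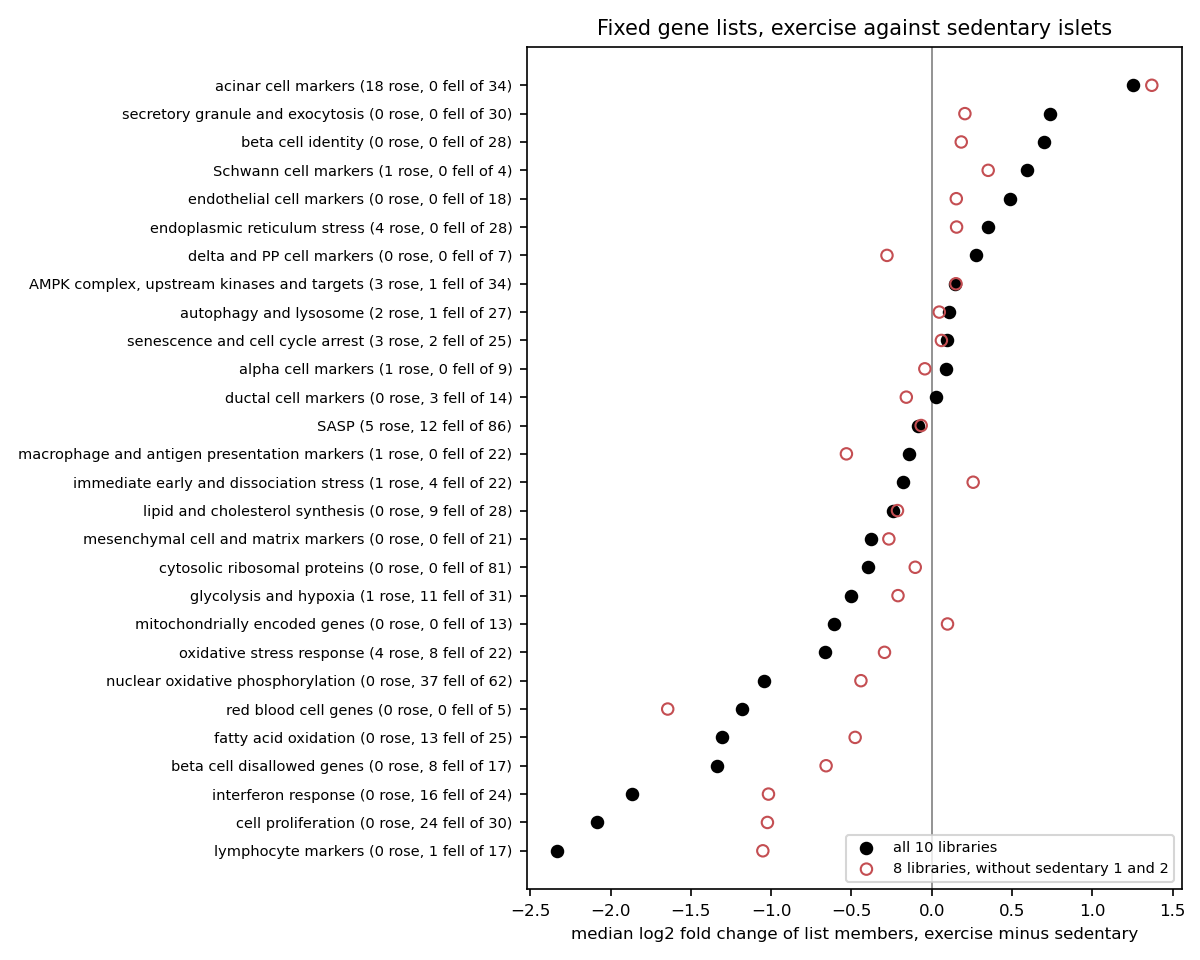
Median log2 fold change of the tested members of 28 fixed gene lists, exercise minus sedentary (horizontal axis), with all 10 libraries (filled points) and without sedentary 1 and 2 (open points). The oxidative phosphorylation median is -1.05 with all libraries and -0.44 without these, and the acinar median is 1.25 and 1.37.

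Proliferation and interferon genes were also lower in exercise. Of 30 proliferation genes 24 fell and 0 rose; adjusted over the list alone, 29 fell. The median was -2.08 (camera adjusted p = 6.4e-12; adjusted p = 0.679 with an estimated correlation). Examples were the cyclin gene Ccne1 (4.99 ± 1.05 to 2.38 ± 0.181 CPM), the thymidine kinase gene Tk1 (9.11 ± 7.85 to 1.23 ± 0.190 CPM), the replication licensing gene Mcm5 (19.2 ± 11.6 to 4.68 ± 1.16 CPM) and the spindle gene Nusap1 (9.58 ± 7.24 to 1.87 ± 0.382 CPM). Of 24 interferon response genes 16 fell and 0 rose; adjusted over the list alone, 18 fell. The median was -1.87 (camera adjusted p = 8.1e-07; adjusted p = 0.679 with an estimated correlation). Examples were Zbp1 (24.8 ± 25.4 to 1.91 ± 0.696 CPM), Irf7 (81.6 ± 110 to 6.27 ± 2.57 CPM), the RNA sensor gene Ifih1 (32.6 ± 27.6 to 7.40 ± 0.0663 CPM) and Oas1a (47.7 ± 66.1 to 3.79 ± 1.68 CPM). In the 8-library fit 17 proliferation genes (median -1.02) and 13 interferon genes (median -1.02) fell. Both lists were highest in sedentary 2 (mean log2 CPM 4.68 and 5.54), where the intestinal list was also highest (8.59). With the intestinal covariate the proliferation and interferon medians turned to 0.25 and 0.38 and neither list passed (camera adjusted p = 0.264 and 0.386). Irf7 was at 277 CPM in sedentary 2 and between 21.2 and 40.8 CPM in the other sedentary libraries. Without sedentary 2 the log2 fold changes of Irf7 and Oas1a, -3.70 and -3.65, were -2.39 and -2.27, and the call of Oas1a was lost without exercise 7, 8, 9 or 10 (highest edgeR adjusted p = 0.0543).

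Stress-response genes rose in part. Of 28 endoplasmic reticulum stress genes 4 rose and 0 fell; adjusted over the list alone, 5 rose. The median was 0.35 (camera adjusted p = 0.00126; adjusted p = 0.679 with an estimated correlation). The rises were those of the asparagine synthetase gene Asns (78.6 ± 21.95 to 183 ± 30.2 CPM), Ern1, encoding the sensor IRE1alpha (88.1 ± 32.3 to 206 ± 23.7 CPM), Herpud1 (198 ± 35.6 to 433 ± 143 CPM) and Eif2ak3, encoding the sensor PERK (49.5 ± 11.9 to 86.3 ± 23.5 CPM). The call of Eif2ak3 was lost without sedentary 1, 2 or 5 or exercise 7, 8 or 9 (highest edgeR adjusted p = 0.0850) and without sedentary 1 and 2 together (0.0833). Its log2 fold change of 0.80 was -0.36 with the intestinal level as a covariate. In the 8-library fit 3 members rose and the list's median was 0.15. The median was -0.01 with library totals alone, and the list's call was lost with the acinar covariate (camera adjusted p = 0.147). With the intestinal covariate the median was -0.35 (camera adjusted p = 0.00249, toward sedentary). Of 22 oxidative stress genes 4 rose and 8 fell (adjusted over the list alone, 4 rose and 12 fell; median -0.67, camera adjusted p = 0.315; 0.50 and 0.00109 with the intestinal covariate). The metallothionein genes Mt1 (101 ± 34.8 to 570 ± 247 CPM) and Mt2 (54.6 ± 23.5 to 342 ± 138 CPM) and the cystine transporter gene Slc7a11 (1.42 ± 0.236 to 3.88 ± 0.888 CPM) rose. Txnip (log2 fold change 1.03), picked after its value was seen, rose too, while Cat fell. Of 22 immediate early and dissociation stress genes 1 rose and 4 fell (adjusted over the list alone, 2 rose and 4 fell; median -0.18, camera adjusted p = 0.885, toward exercise). The list's median lay between -0.32 and 0.13 with 1 library left out. The list passed toward sedentary with the acinar covariate (median -0.57, camera adjusted p = 0.0363). The rise was that of Btg2, and the falls were those of the chaperone genes Dnajb1, Hspa1a and Hspa1b and the transcription factor gene Klf4 (log2 fold changes -0.84, -2.51, -2.89 and -1.78). The call of Klf4 was lost without exercise 7, 8 or 9 (highest edgeR adjusted p = 0.0595).

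Of 27 autophagy and lysosome genes 2 rose and 1 fell, also when adjusted over the list alone (median 0.11 and -0.23 with library totals alone, camera adjusted p = 0.243). Map1lc3b, whose product coats autophagosomes, rose from 94.9 ± 13.3 to 141 ± 10.3 CPM, as did Ulk1, and Atg12 had a log2 fold change of -0.76 that did not pass. The call of Map1lc3b was lost without exercise 6, 7 or 8 (highest edgeR adjusted p = 0.0557). None of 81 cytosolic ribosomal protein genes passed over all genes or adjusted over the list alone. The list stood lower in exercise (median -0.40, camera adjusted p = 3.7e-06; adjusted p = 0.679 with an estimated correlation). Log2 fold changes were -0.80 for Rps15a, -0.44 for Rpl7l1, -0.64 for Rpl27 and -0.58 for Rps27. In the 8-library fit the ribosomal median was -0.10 and the list test did not pass (camera adjusted p = 0.180), and with the intestinal covariate the median was 0.29 (camera adjusted p = 6.7e-05, toward exercise).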

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

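The tests on intestinal RNA, library size, dilution and the share of endocrine RNA were chosen after related results had been seen, and the other tests before theirs. In 44 of 336 groups of 5 libraries 1 library lay far from the others. Independent, normally distributed values would give about 1 in 20 groups, here 16.8. CPM values are skewed and many of these genes move together, so 44 against 16.8 is no test of chance.

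The first pattern was the lower level of most changed genes in exercise (1745 of 2119), intestinal transcripts among them. Of 100 splits of the 10 libraries 1, the real one, gave as many genes, and the highest other gave 1. This argues against chance without excluding it, since only 126 distinct splits exist and the genes are not independent. Thinning every library to the smallest total left 1712 lower genes, which argues against library size. Intestinal mucosa RNA in the sedentary libraries is a candidate explanation: of 1327 genes lower in exercise without sedentary 1 and 2, list members left out, 82.8% (95% exact binomial interval 80.7 to 84.8) went up with the intestinal list among the 5 exercise libraries, against 47.4% of all 15652 genes and 18.5% of the 644 higher genes. Genes are not independent, so the interval is too narrow, and the intestinal level shared much of its variance with the group (r squared 0.801). How much of the fall it could account for, and an effect of exercise on the islets, which was not tested apart from it, stay open.

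The count of 14 changed lists did not exceed chance: 39 of 100 splits gave as many, the real one included, and the highest other gave 19.

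The second pattern was the higher level of the beta cell identity list. Its median was 0.70, and 0.18 without sedentary 1 and 2. These were the libraries lowest in the list (mean log2 CPM 4.66 and 6.35 against 7.89 to 8.21 in sedentary 3 to 5), so that leaving them out had to lower the median and tests no explanation. A low endocrine share of these libraries, intestinal RNA in the sedentary libraries and an effect of exercise stay open.

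Among shares and list levels, insulin took 8.03% of counts in exercise 9 (others 14.2 to 16.1%), the AMPK list had a mean log2 CPM of 4.84 in exercise 9, the interferon list 5.54 in sedentary 2 and the immediate early list 3.997 in sedentary 1. In sedentary 2, intestinal and ductal genes stood apart: Defa36 at 24.9, Defa23 at 153, Defa30 at 137, Defa24 at 289, AY761184 at 67.2, Slc5a12 at 11.2, Ang4 at 20.6, Itln1 at 154, Cftr at 121 and Sox9 at 23.04 CPM. Interferon genes did so in the same library, with Irf7 at 277, Ifih1 at 80.8 and Oas1a at 165 CPM, and Gem was low there at 1.47 CPM. In exercise 6, Defa36 was at 0.112, Defa23 at 1.56, Defa30 at 1.51, Defa24 at 3.69, AY761184 at 0.838, Ang4 at 0.224, Itln1 at 2.35, Pgc at 1.84, Cftr at 5.03 and Oas1a at 6.76 CPM, each above the other exercise libraries, as were Ccl2 at 23.5 and Cyc1 at 51.2 CPM. In sedentary 1, Pgc was at 2842 CPM, the lymphocyte genes Cd8a, Cd3g, Nkg7 and Cd5 were at 47.6, 42.8, 15.1 and 28.4 CPM, and Bcl2l1 was low at 23.01 CPM. In exercise 9, Btg2 was at 206, Gem at 17.5 and Rps15a at 115 CPM. Single genes stood apart in exercise 7 (Acadm at 12.5 CPM), exercise 8 (Stx1a at 5.06 CPM) and exercise 10 (Asb9 at 2.34 and Il15 at 0.928 CPM).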

How the results depend on the processing

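The fits without sedentary 1 and 2, with the intestinal or granule covariate, without acinar genes in the scaling and with thinned libraries were chosen after seeing the data. No paired analysis was possible because the replicate numbers 1 to 10 are not shared between groups. Higher and lower genes numbered 374 and 1745, and stayed within 1.5 times of this with RLE factors (412 and 1701), upper-quartile factors (499 and 1778), no filter (279 and 1739), a filter at 1 CPM (379 and 1691), robust edgeR (362 and 1694), thinning (375 and 1712) and scaling without acinar genes (424 and 1638). They were 159 and 4408 with library totals, 163 and 674 with a surrogate variable, 138 and 519 with the granule covariate, 1097 and 2642 with DESeq2, 177 and 339 with limma-voom, 868 and 2024 with quality weights, and 644 and 1362 without sedentary 1 and 2. The edgeR fits with the acinar and the intestinal covariate called 0 and 0 genes, with 1867 and 279 at an unadjusted p under 0.05; both covariates follow the group. Library totals moved the median log2 fold change of all genes to -0.34 and upper-quartile factors to 0.11. Elsewhere the cause was not tested.

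Leaving out 1 library gave 132 to 889 higher and 800 to 2721 lower genes. Higher genes moved by over 1.5 times without sedentary 2 (231), 4 (889) or 5 (242) and without exercise 6 (167), 7 (132), 8 (151) or 9 (155), and lower genes without sedentary 1 (1059) or 4 (2721) and without exercise 6 (1015), 7 (828), 8 (800), 9 (871) or 10 (955). Of 84 named genes that passed, 50 passed in all 10 such fits and 34 were lost in at least 1 (highest edgeR adjusted p = 0.0869). Changed lists numbered 13 to 17 in these fits, 15 with the acinar covariate (10 shared with the 14 in direction) and 15 with the intestinal covariate (2 shared). They numbered 9 with the surrogate variable, 9 with the granule covariate, 6 with fry's directional and 16 with its mixed test, and 0 with an estimated correlation. The acinar share difference ranged from 10.9 to 15.4 points and the 10 most abundant genes from 9.09 to 13.7; the first was lost without exercise 6 or 9 and the other without any 1 exercise library (exact permutation adjusted p = 0.0595). The mitochondrial difference ranged from -2.90 to -1.69 and was lost without any 1 exercise library (highest adjusted p = 0.225, exact permutation), insulin from -0.746 to 4.34, glucagon from -0.419 to 0.0114, the senescence score from 0.01 to 0.06 and the SASP score from -0.14 to 0.05. Without sedentary 1 and 2 the glucagon difference was -0.627 (now past), the mitochondrial -0.640 and that of the 10 most abundant genes 6.82 (both no longer past). The insulin difference was then -4.34 and did not pass. The senescence score differed by 0.15 with genes scaled to unit variance (exact permutation adjusted p = 0.0317) and by -0.31 with library totals.

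With the intestinal covariate 37 of the 84 named genes that had passed changed sign, none past the threshold. Sign changes of named genes that had not passed were not counted. Among the 37 were Pgc 3.48, Slc16a1 0.40, Ldha 0.048, Cftr 0.27, Slc4a4 0.65, Krt19 0.70, Cidec 0.86, Cdkn2b 0.76, Gadd45b -0.24, Il18 0.39 and Il15 0.16. Others were Dpp4 0.019, Ppargc1a 0.38, Camkk2 -0.12, Acaa2 0.53, Decr1 0.73, Acadm 0.64, Idi1 0.11, Stard4 0.32, Cycs 0.69, Cox5a 0.82, Uqcrc1 0.61 and Cyc1 0.85. So were Car9 0.25, Pfkfb4 0.28, Egln3 0.20, Eif2ak3 -0.36, Tk1 0.27, Nusap1 0.24, Ifih1 0.26, Oas1a 0.058, Hspa1a 0.57, Hspa1b 1.03 and Klf4 0.60. Among lists that passed with or without this covariate, medians that changed direction were beta cell identity -1.08, disallowed genes 0.28, delta and PP cells -1.38, endothelial -0.69 and fatty acid oxidation 0.73. Others were oxidative phosphorylation 0.62, mitochondrially encoded 0.85, glycolysis 0.28, endoplasmic reticulum stress -0.35, oxidative stress 0.50, proliferation 0.25, interferon 0.38, secretory granule -1.16 and ribosomal 0.29. For the mesenchymal (median -1.16) and macrophage (-0.63) lists camera's direction turned and the lists passed, as with the acinar covariate for the macrophage (-0.47, camera adjusted p = 0.0467) and immediate early (-0.57, 0.0363) lists; these medians were below 0 with and without the covariates. In counts simulated at this depth and spread, 18 of 100 genes changed 2-fold were recovered. Far fewer genes were changed there than the 2119 called here, so recovery in these data may differ.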

Other observations

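Both lists described here were written after the data were seen, and the dilution tests on them were chosen after related results; the tests with the acinar covariate were set before theirs, apart from those with an estimated correlation, which were made a condition for excluding acinar RNA after their values and the others had been seen.

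Genes that respond to glucocorticoids, the adrenal steroid hormones, were higher in exercise. Of 22 tested members 10 rose and 0 fell (adjusted over the list alone, 13 rose and 1 fell), with a median log2 fold change of 0.95 (limma camera adjusted p = 1.2e-08; adjusted p = 0.0884 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 40.6 ± 18.0 to 197 ± 59.6 CPM and the transcription factor gene Klf9 from 48.5 ± 19.7 to 107 ± 31.3 CPM, and Zbtb16, Fam107a, Hif3a, Mt1 and Mt2 are members. Tsc22d3, another target of the receptor, had 48.6 ± 8.46 and 46.7 ± 14.3 CPM and Sgk1 68.5 ± 38.5 and 26.4 ± 12.9 CPM, neither of which passed (edgeR adjusted p = 0.858 and 0.0545). Of the list, 6 members also stood in the fixed lists. Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were higher as well: of 31 tested members 15 rose and 0 fell (adjusted over the list alone, 21 rose and 1 fell; median 0.75, camera adjusted p = 1.5e-10; adjusted p = 0.0884 with an estimated correlation). Nupr1 rose from 245 ± 53.2 to 889 ± 307 CPM, the serine synthesis gene Phgdh from 48.4 ± 12.2 to 114 ± 20.4 CPM and the translation repressor gene Eif4ebp1 from 16.5 ± 2.09 to 41.4 ± 8.95 CPM, while Atf4 itself had 186 ± 48.2 and 217 ± 20.4 CPM (edgeR adjusted p = 0.416). Of this list, 9 members also stood in the fixed lists.

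Both lists were written on these data and hold some of the largest rises, so that their excess over other genes decides nothing about dilution by intestinal RNA. Without sedentary 1 and 2 the glucocorticoid median exceeded that of the secretory granule list (0.21) by 0.60 (95% bootstrap interval over members 0.30 to 1.88) and the ATF4 median by 0.36 (0.06 to 0.74). With the acinar covariate the glucocorticoid median went from 0.95 to 0.49 (0.01 to 1.35) and the ATF4 median from 0.75 to 0.76 (0.29 to 1.01), and both passed at the preset correlation (camera adjusted p = 0.00229 and 8.2e-07). These intervals and p-values take members as nearly independent, but their estimated correlation in that fit was 0.354 and 0.286. With it neither list passed (camera adjusted p = 0.286 and 0.161), as neither had without the covariate (0.0884 each). The rule set beforehand, an interval above 0 and a list test past the threshold, was met by both. For ATF4 targets 26 of 31 members were above 0 with the covariate and the median was unchanged. This decides nothing about acinar RNA, since the list was written on these data and the covariate follows the group. The glucocorticoid median fell and its interval nearly reached 0, so acinar RNA stays open there.

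In exercise 6, 7, 8, 9 and 10 the mean log2 CPM of the glucocorticoid list was 5.29, 4.59, 4.48, 5.60 and 4.36 and that of the acinar list 11.15, 10.69, 10.55, 11.69 and 10.28, in the same order of libraries, while ATF4 targets were at 5.71, 5.64, 5.46, 5.87 and 5.51. In sedentary 1, 2, 3, 4 and 5 the glucocorticoid list was at 3.11, 3.33, 3.65, 3.59 and 3.79, the acinar list at 10.30, 9.21, 9.70, 9.88 and 9.44 and ATF4 targets at 4.53, 4.59, 4.98, 5.11 and 4.99. Sedentary 1 and exercise 10 thus had similar acinar levels (10.30 and 10.28) and different glucocorticoid (3.11 and 4.36) and ATF4 levels (4.53 and 5.51). This pair was picked after its values were seen. Its intestinal levels differed too (7.86 and 3.84), so the pair decides nothing. Within exercise the glucocorticoid and acinar lists ranked the 5 libraries alike, but not within the sedentary group. ATF4 targets followed the acinar order within exercise too, apart from exercise 8 and 10. Less dilution by intestinal RNA, more acinar RNA and an effect of exercise stay open for both lists. Hormone levels, handling and the time of sampling were not analysed here.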
